A study of Danio rerio with 10 samples.

How the data were processed

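Total RNA from zebrafish hearts kept in hypoxia or normoxia was labelled with biotin and read on Affymetrix Zebrafish GeneChips, 1 array per labelled RNA sample. The series holds 10 arrays, 5 per group. The labels give 8 biological samples, 4 per group, and 1 further array per group, array 5, as a technical repeat of biological sample 2 of that group. The description of hypoxia array 5 also gives the number 4, and this array was taken as a repeat of hypoxia 2, from which its SD of log2 differences was 0.105, against 0.353 from hypoxia 4. The age and sex of the fish, the oxygen level, the length of the exposure and the number of hearts per sample are not given in the sources used here.

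The deposited table gives 1 intensity per probe set and array for 15617 probe sets, and the software and settings that made it are not given in the sources used here. The values were on a linear scale, with 7.86 to 10.1% of them at or below 0 on each array, a lowest value of -116 and a highest of 9979, which is the range of background- or mismatch-subtracted signals. Median intensities ran from 36.2 to 51.6 between arrays, so the columns had not been brought to a common level. The deposited records of each array held another unit, text on the chip type, the fluidics station and the time of hybridization, with no expression value. From these records the arrays fell into 3 hybridization runs. Run 1 held arrays 1 and 2 of both groups, run 2 held arrays 3 and 4 of both groups and run 3 held array 5 of both groups, the technical repeats of RNA also in run 1, whose wash records end in an abort.

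Before the data were examined, the test, the gene lists, the rule for named genes and most alternatives had been fixed. Arrays whose log2 medians differed by more than 0.1 were to be quantile normalized, which applied here. The planned step of adding 1 before taking log2 cannot handle values under 0, so values were quantile normalized on the linear scale, 1 was added and any result under 1 was set to 1 before log2. The 115 AFFX control probe sets were left out, as were the probe sets in the lowest 30% of mean log2 intensity, those under 4.02, which left 10851. A background bound of 27.0 intensity units, 2 times the background SD of 13.5 estimated from the negative values, was used to mark arrays on which a gene was not above background.

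The number of independent samples was lowered from 4 to 3 per group. Over 2247 bright probe sets, those with a mean log2 intensity of at least 8, the SD of log2 differences between arrays was at or below that of the less alike of the 2 technical pairs (0.151) for 2 pairs of arrays labelled as separate biological samples, hypoxia 1 with hypoxia 4 (0.112) and normoxia 3 with normoxia 4 (0.0927). Only the latter was also below the other technical pair (0.105). Each of these pairs was averaged and counted as 1 sample (hypoxia 1/4 and normoxia 3/4), and array 5 was averaged with array 2 of its group. The same 2 pairs met the rule under each of the 5 scalings tried. The rule was set after a count with the 8 samples as labelled had been seen and before any count with 3 against 3. The count with 8 samples as labelled is given beside the main one.

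Hypoxia was compared with normoxia in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjusted p under 0.05 over the 10851 probe sets. Differences are hypoxia minus normoxia on the log2 scale with the moderated SE, and group values are means with the SD over n = 3 samples. For a single measure, 3 against 3 samples cannot give an exact permutation p under 0.1, so the calls rest on the spread that limma pools over probe sets. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for names and figures.

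The 27 gene lists covered glycolysis, the hypoxia response, oxidative phosphorylation, the TCA cycle, fatty acid oxidation, sarcomere, calcium and conduction, cardiac stress, red blood cell, globins outside blood, cell cycle, heat shock and chaperones, antioxidant, cytosolic ribosome, proteasome, extracellular matrix, endothelium, leukocyte, epicardium, skeletal muscle, liver, egg and yolk, gill and skin epithelium, apoptosis and p53, insulin-like growth factor, circadian clock and immediate early genes. They were written by hand from textbook knowledge, and some genes stand on more than 1 list. A gene with several probe sets was represented by that of the highest mean. The 25 lists with at least 5 measured genes were tested with limma camera at its preset inter-gene correlation of 0.01, which compares a list with the other genes, and adjusted over the lists. The epicardium list and that of globins outside blood were smaller and are given gene by gene.

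Named genes follow 1 rule. They are the 10 largest rises and 10 largest falls among called probe sets with exactly 1 symbol and non-overlapping groups, the 2 called members of each list with the largest change, and a fixed panel of 12 genes (ldha, vegfaa, hif1ab, egln3, igfbp1a, mb, nppa, hmox1a, hsp70l, pcna, myl7 and gapdh). This gave 56 genes. Of the panel, 9 genes had a probe set among those tested, and nppa, hmox1a and hsp70l were not tested here. Other genes in the text were picked after their values were seen, as examples of a list.

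Of the 15502 probe sets other than controls, a reference table for this array pairs 10795 with 1 gene symbol, 135 with several and 4572 with none, for 8793 distinct symbols. Of the gene identifiers, 10711 were found in a reference gene table of assembly GRCz12tu, which was used for names only and changed 1 symbol. No genome position is given. On the array, 663 list genes had a probe set.

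The procedure was tested on simulated data, 10 sets of 10 arrays made from 6 independent samples, with the measured means, the pooled spreads and near-identical arrays as in the data, and with 200 of the 10851 probe sets changed. At a log2 change of 0.5, 1 and 2, the share called with the 6 samples was 9.13, 51.1 and 85.4%. All calls on changed probe sets had the right sign, and 5.88% of calls fell on unchanged ones. When the same simulated arrays were analysed as 8 separate samples, 29.8% of calls fell on unchanged probe sets. Since the near-identical arrays were built in, this cannot tell whether the real pairs share RNA. With the spreads as measured and not pooled, the share called with the 6 samples was 8.97, 42.9 and 82.8%, and 4.91% of calls fell on unchanged probe sets. A list shifted by 0.5 was called in 10 of 10 simulations and 0 of 200 unshifted lists were called, with no correlation between simulated genes.

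Alternatives were the deposited values without normalization, cyclic loess and median scaling, an offset of 50, other filters on low values, the variance model, other uses of array 5, array weights, the sample number as a block, the hybridization run as a block with all 10 arrays and the sample as a random block, each sample left out, other thresholds, 1 probe set per gene, an estimated inter-gene correlation, the limma fry test and all probe sets of list members. The samples as labelled, a floor at the background bound and both arrays of a near-identical pair left out together were added after the data had been seen. All 10 splits of the 6 samples into 3 and 3 were also run. Array data limit precision by the number of samples, and signals near background or near the top of the scale understate changes.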

Results

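Expression was measured on 10 arrays of zebrafish heart RNA, 5 from fish in hypoxia and 5 from fish in normoxia, to find which heart transcripts differ under low oxygen. The labels name 4 biological samples per group and a technical repeat of sample 2 in each group. Median intensity per array was 36.2 to 51.6. The number of arrays limits the precision.

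Repeat arrays of the same RNA differed little. Over 2247 bright probe sets, the SD of log2 differences was 0.105 for hypoxia 2 and its repeat (r = 0.996) and 0.151 for normoxia 2 and its repeat (r = 0.992). Within a group, 2 further pairs of arrays labelled as separate biological samples had SDs in or below this range, 0.112 for hypoxia 1 and hypoxia 4 and 0.0927 for normoxia 3 and normoxia 4. The remaining 16 pairs ranged from 0.268 to 0.635, and the 25 pairs between groups from 0.455 to 0.827. Each near-identical pair was therefore counted as 1 sample, which left 3 samples per group (hypoxia 1/4, 2 and 3, and normoxia 1, 2 and 3/4).

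**Figure D1:**
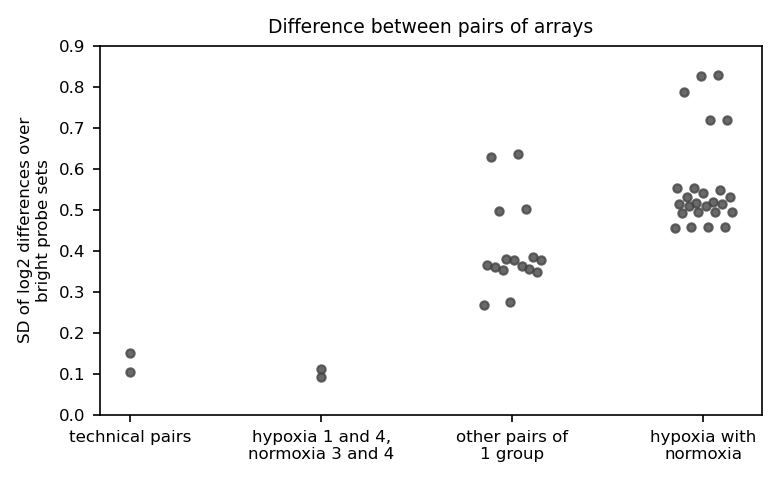
SD of the log2 difference over 2247 bright probe sets for each pair of the 10 arrays, by kind of pair. The pairs hypoxia 1 with 4 and normoxia 3 with 4 sit with the technical pairs, at 0.112 and 0.0927, and the other 16 pairs within a group start at 0.268.

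Many genes of oxidative metabolism had lower transcript levels in hearts from hypoxic fish, 19 of 22 measured genes of fatty acid oxidation, 8 of 23 of the TCA cycle and 34 of 74 of oxidative phosphorylation, and 7 of 27 hypoxia response genes and 7 of 18 red blood cell genes rose. These counts were each 0 without hypoxia 3, which leaves fewer samples to fit, or with no intensity trend in the fit. In the same order they were 1, 0, 1, 1 and 1 without normoxia 1, again with fewer samples. For the deposited values they were 12, 1, 2, 2 and 1. As lists these passed camera at its preset correlation but not with an estimated correlation (adjusted p = 0.251 to 0.283). The limma fry test, which asks whether a list's genes move on balance one way, called each of them (adjusted p = 0.00377 to 0.0260). For fatty acid oxidation, the breakdown of fatty acids in mitochondria, the list mean was 8.97 ± 0.05 in hypoxia against 9.74 ± 0.11 in normoxia (log2 intensity, SD, n = 3). The prolyl hydroxylase gene egln3, whose product acts on HIF alpha subunits, was 4.0-fold higher, at 9.23 ± 0.13 against 7.23 ± 0.34 (SD, n = 3). The embryonic beta globin gene hbbe2 was 3.46-fold higher, at 9.07 ± 0.22 against 7.28 ± 0.27 (SD, n = 3). The immediate early gene fosab, a component of the AP-1 transcription factor, fell by 2.78 log2, from 8.30 ± 0.76 in normoxia to 5.53 ± 0.61 in hypoxia (SD, n = 3). Its other probe sets gave -2.61 and -1.38, both called, and -2.28, not called (adjusted p = 0.0574 from limma).

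Of 10851 probe sets tested, 432 (3.98%) changed between hypoxia and normoxia in limma at adjusted p under 0.05, 105 higher and 327 lower in hypoxia, and 2300 had an unadjusted p under 0.05. The changes were by at least 2-fold for 46 of those higher and 60 of those lower. Groups did not overlap for 2953 probe sets, 27.2% against 10% by chance, and these included all 432. The 343 called probe sets with 1 symbol stood for 323 genes, 81 higher and 242 lower. The share of called probe sets that were lower was 75.7%, and it was 58.3% of 103 with the deposited values, 62.2% of 370 with cyclic loess and 90.4% of 790 with median scaling, under which the median of all probe sets moved from -0.05 to -0.14. With all 10 arrays and the sample as a random block 1012 were called, and 869 when the hybridization run was added to that fit as a block. Run 1 alone, 2 samples against 2, gave 0 calls in limma with 1655 at unadjusted p under 0.05. The count fell when any 1 counted sample was left out, each a fit to fewer samples. It was 1 without hypoxia 3, 226 without hypoxia 2, 87 without hypoxia 1/4, 23 without normoxia 1, 96 without normoxia 2 and 82 without normoxia 3/4. Without hypoxia 3 the list means of fatty acid oxidation, oxidative phosphorylation and the TCA cycle were -0.78, -0.33 and -0.34. With all 6 samples they were -0.78, -0.33 and -0.35. The cell cycle mean dropped from 0.51 to 0.10 without hypoxia 3. With the 8 samples as labelled the count of probe sets was 1397, of which 429 were among the 432. Of the 49 called genes that the naming rule took, 48 lost the call without hypoxia 3 and 41 without normoxia 1, 25 kept it in a refit with values under the background bound set to that bound, in which genes above the bound on all arrays, such as pdk2b (adjusted p = 0.0889), lost it as well, and kif20a kept it in all 27 settings.

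Among the largest rises were genes known from the liver. The C-reactive protein gene crp (adjusted p = 0.0224), an acute-phase gene of the liver, was higher by 4.36 ± 0.57 log2 (SE, n = 3). The hemopexin gene hpxa, whose product binds free heme, rose by 4.35, and the haptoglobin gene hp, whose product binds free haemoglobin, by 2.16, and both are on the liver list, which spanned 3.59 log2 between the normoxia samples. The uncoupling protein gene ucp1 rose by 3.59 (adjusted p = 0.0463, and 3.56 at 0.0871, not past the threshold, in the refit with values at the background bound), the carboxylesterase gene ces2a by 3.0, the epithelial adhesion gene epcam by 2.88 and the cytochrome P450 gene cyp1a by 2.31. In that refit hpxa (adjusted p = 0.0632), hp (0.0581), epcam (0.0507) and cyp1a (0.0507) also lost the call, while crp (0.0426) and ces2a (0.0451) kept it. Like the liver list mean (5.38), crp (4.62), hpxa (4.85), ucp1 (4.63) and ces2a (4.71) had their lowest value in normoxia 1, and their lowest within hypoxia in hypoxia 1/4. The other rises named so far did not follow this pattern. The liver list gene hp (6.31) and epcam (5.39) were lowest in normoxia 2, and cyp1a was lowest within hypoxia in hypoxia 3 (8.85). The gene kif20a, a kinesin of cell division, had the smallest p, with 11.25 ± 0.28 in hypoxia against 8.69 ± 0.08 in normoxia (SD, n = 3, adjusted p = 0.00553 from limma). Both elf3, an epithelial transcription factor gene, and wu:fb63a08 were under the background bound on all 5 normoxia arrays. With values at that bound elf3 was at least 2.90-fold higher (adjusted p = 0.149) and wu:fb63a08 at least 13.0-fold higher (adjusted p = 0.0810), neither past the threshold.

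The chymotrypsinogen gene ctrb.1, a digestive protease gene of the pancreas, had the largest fall and fell by 3.16 log2 (SE 0.32, n = 3, adjusted p = 0.0151 from limma). The pyruvate dehydrogenase kinase gene pdk2b fell by 1.86, and jdp2b, whose product dimerizes with Jun, fell by 1.69. The glucose-6-phosphate transporter gene slc37a4b was under the background bound on 4 of 5 hypoxia arrays, and with values at that bound was at least 2.22-fold lower (adjusted p = 0.0295). The remaining genes among the 10 largest falls were ntd5 at -2.20, the synaptotagmin gene syt1a at -1.76, ankrd9 at -1.76, the phosphoesterase gene mpped2 at -1.39 and the enoyl-CoA isomerase gene ech1 at -1.42. The gene ech1 was under the background bound on 2 of 5 hypoxia arrays. In the refit with values at the background bound ech1 had -1.36 and was not called (adjusted p = 0.0700), and another probe set of ech1 gave -0.52 and was not called (adjusted p = 0.280). Of the 10 largest falls, fosab (adjusted p = 0.0587), ntd5 (0.0501), syt1a (0.0680), ankrd9 (0.0507) and pdk2b (0.0889) also lost the call in that refit. The genes ctrb.1 (0.0283), jdp2b (0.0454), mpped2 (0.0452) and slc37a4b kept it.

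**Figure D2:**
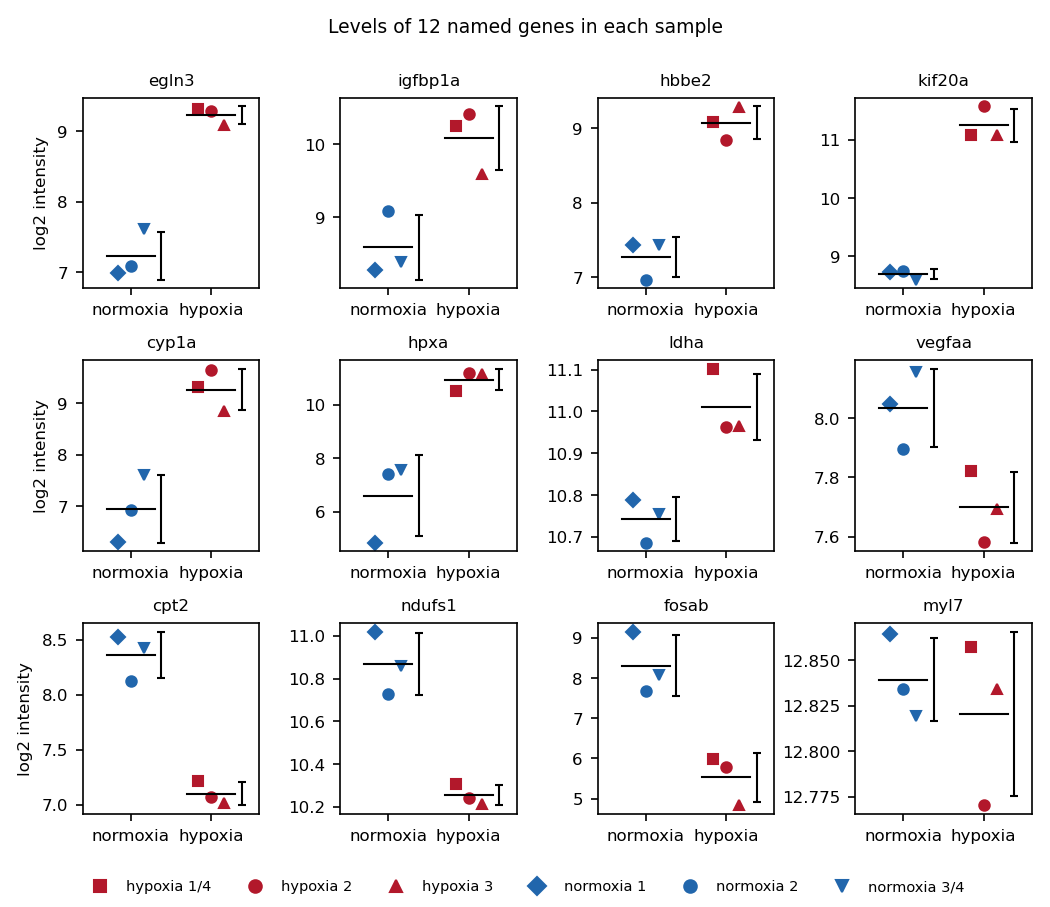
Log2 intensity of 12 named genes in each of the 3 hypoxia and 3 normoxia samples, with the group mean as a line and the SD as a bar (n = 3), each panel on its own scale. The samples of egln3, hbbe2 and kif20a are all higher in hypoxia, those of cpt2, ndufs1 and fosab all lower, and myl7 overlaps between groups.

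All 22 fatty acid oxidation genes lay below 0. Over all genes tested 19 fell, and adjusted over the list alone 22 fell. The carnitine palmitoyltransferase gene cpt2, which brings fatty acids into the mitochondrial matrix, fell by 1.26, although its other probe set gave -0.53 and was not called (adjusted p = 0.373). The acyl-CoA dehydrogenase gene acads fell by 1.2, decr1 by 1.13 and the carnitine carrier gene slc25a20 by 0.99. The fatty acid binding protein gene fabp3 had -0.24 and was not called. The list mean was -0.78 (camera adjusted p = 2.60e-20, adjusted p = 0.251 with an estimated correlation), with -0.82, -0.71 and -0.71 in runs 1, 2 and 3. The runs are not independent repeats here or for the lists below. Run 3 holds repeats of RNA also in run 1, and hypoxia 1 of run 1 was counted as 1 sample with hypoxia 4 of run 2.

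Oxidative phosphorylation and the TCA cycle, the mitochondrial steps that follow, were lower by less. Of 74 oxidative phosphorylation genes, 34 fell (64 adjusted over the list alone), among them the complex I subunit gene ndufs1 at -0.61, the cytochrome c gene cycsb at -0.56, the complex IV subunit gene cox5ab at -0.72 and the ATP synthase gene atp5mc1 at -0.53. The complex IV subunit gene cox4i2 had 0.62 and was not called. The mean was -0.33 (adjusted p = 4.36e-28, adjusted p = 0.283 with an estimated correlation), and -0.31, -0.35 and -0.26 in runs 1, 2 and 3. Of 23 TCA cycle genes, 8 fell (19 adjusted over the list alone). The gene sucla2 had -0.69 (-1.03 at its other probe set, also called), ogdha -0.68, sdha -0.55 and the citrate synthase gene cs -0.35. The TCA cycle mean was -0.35 (adjusted p = 1.84e-10, adjusted p = 0.251 with an estimated correlation), and -0.33, -0.35 and -0.32 by run. Under median scaling the oxidative phosphorylation mean was -0.57 and the TCA cycle mean -0.56, and for the deposited values they were -0.50 and -0.48, so their size depends on the scaling. All 3 lists stayed below the median of all genes under the 3 other scalings.

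Hypoxia response genes were higher as a list, with 7 of 27 higher and 0 lower at the threshold (8 and 0 adjusted over the list alone, 4 and 2 under median scaling). Beside egln3, the insulin-like growth factor binding protein gene igfbp1a rose by 1.49 ± 0.28 log2 (SE, n = 3), hif1al2 by 1.42, the collagen prolyl hydroxylase gene p4ha1b by 0.98, the lysyl hydroxylase gene plod1a by 0.64, the HIF prolyl hydroxylase gene egln1b by 0.59 and the mitophagy receptor gene bnip3lb by 0.58. The angiogenic factor gene vegfaa had -0.33 (adjusted p = 0.162), with all hypoxia samples below all normoxia samples, and hif1ab had -0.10 (adjusted p = 0.509). The list mean was 0.29 (adjusted p = 0.00507, adjusted p = 0.283 with an estimated correlation), and 0.36, 0.24 and 0.43 by run. It was 0.21 for the deposited values and 0.13 under median scaling.

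Glycolysis genes went both ways and the list was not past the threshold (mean 0.13, adjusted p = 0.381, and -0.07 under median scaling). The phosphofructokinase gene pfkma rose by 0.97 and gapdhs by 0.39, while pgam2 and pgam1b, both phosphoglycerate mutase genes, had -0.54 and -0.52, the aldolase gene aldoab -0.29 and the lactate dehydrogenase gene ldhba -0.28, all 4 past the threshold. That made 2 higher and 4 lower of 25, and 4 and 5 adjusted over the list alone. The lactate dehydrogenase gene ldha had 0.27 (adjusted p = 0.0702), with 0.09 for the deposited values and 0.02 under median scaling. All its hypoxia samples lay above all its normoxia samples, while 27.2% of the probe sets tested had groups that did not overlap. The gene gapdh had 0.06 (adjusted p = 0.576, -0.07 under median scaling).

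Red blood cell genes were higher as a list, with 7 of 18 past the threshold (10 adjusted over the list alone) and all 18 above 0. Among the called members, after hbbe2 came the nucleotidase gene nt5c2l1 at 1.22, the biliverdin reductase gene blvrb at 1.16, alas2, the gene for the first enzyme of heme synthesis in red cells, at 1.13, the membrane skeleton gene epb41b at 0.87, the anion exchanger gene slc4a1a at 0.72 and the carbonic anhydrase gene cahz at 0.61. The embryonic alpha globin gene hbae3 had 0.15 and was not called. The adult globin genes hbaa1 and hbba2, near the top of the intensity scale, had 0.09 and 0.06 and were not called. The mean was 0.71 (adjusted p = 5.39e-11, adjusted p = 0.283 with an estimated correlation), and 0.69, 0.86 and 0.66 by run. Of the globins outside blood, the myoglobin gene mb was measured, at 0.04 (adjusted p = 0.493), with -0.04 for the deposited values and -0.12 under median scaling.

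Cytosolic ribosome genes had a mean of 0.08 (adjusted p = 1.84e-10, adjusted p = 0.298 with an estimated correlation). It was 0.02 for the deposited values, no longer past the threshold (adjusted p = 0.0713), and turned to -0.06 under median scaling, also not past it (adjusted p = 0.877). Under cyclic loess it was 0.21 (adjusted p = 2.16e-26). Of 72 genes rpl23a rose, by 0.26, and 0 rose adjusted over the list alone. By run the means were 0.08, 0.09 and 0.04.

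Immediate early genes, which respond within minutes to stimuli and handling, were lower as a list, with 4 of 25 lower (10 adjusted over the list alone). Beside fosab, the cytokine signalling inhibitor gene socs3a fell by 1.34, the nuclear receptor gene nr4a1 by 1.27 and btg2 by 1.09. The mean was -0.64 (adjusted p = 1.04e-05, adjusted p = 0.336 with an estimated correlation), and -0.75, -0.42 and -0.50 by run. Circadian clock genes were not past the threshold as a list, with a mean of 0.00 and a median of -0.02 (adjusted p = 0.887). Of 21, nfil3-6 fell by 1.0 (its other probe set had -0.77 and was not called), and rorcb, under the background bound on the normoxia arrays, was called with a rise that shrank to at least 1.3-fold (adjusted p = 0.159, not past the threshold) with values at that bound. Adjusted over the list alone 1 rose and 2 fell.

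Stress gene lists went both ways. Heat shock and chaperone genes had 1 of 23 higher and 1 lower (3 and 4 adjusted over the list alone). These were the paralogous chaperone genes hsp90aa1.2 at 0.98 and hsp90aa1.1 at -0.93. The list mean was -0.02 while camera ranked it upward (adjusted p = 0.776), and the mean turned to 0.03 under cyclic loess. Antioxidant genes had 1 of 22 higher, the peroxiredoxin gene prdx2 at 0.70, and 2 lower, both mitochondrial, the peroxiredoxin gene prdx3 at -0.66 and the superoxide dismutase gene sod2 at -0.60 (3 and 3 adjusted over the list alone). Their mean was 0.12 (adjusted p = 0.234, -0.08 under median scaling). Among 19 apoptosis and p53 genes the cell cycle inhibitor gene cdkn1bb rose by 0.51 and gadd45ba fell by 0.71 (6 and 1 adjusted over the list alone), with a mean of 0.08 (adjusted p = 0.0774, -0.05 under median scaling). The other probe set of cdkn1bb gave 0.47 and was not called (adjusted p = 0.194). Proteasome genes had 1 of 40 lower, psmd11b at -0.50 (0 adjusted over the list alone), and a mean of -0.06 (adjusted p = 0.776), which passed under median scaling (-0.25, adjusted p = 0.00856).

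Sarcomere genes were lower as a list by less than fatty acid oxidation genes, with 2 of 15 lower (6 adjusted over the list alone). These were the myosin heavy chain gene myh7 at -0.89 and the titin gene ttn.2 at -0.56 (-1.10 at its other probe set, also called). The myosin light chain gene myl7, near the top of the scale, had -0.02 (adjusted p = 0.813, 0.10 under cyclic loess). The mean was -0.27 (adjusted p = 0.000348, adjusted p = 0.283 with an estimated correlation, 0.0566 under cyclic loess), and -0.24, -0.28 and -0.32 by run. It was -0.39 for the deposited values and -0.46 under median scaling. Of 11 calcium and conduction genes, 3 fell (3 adjusted over the list alone), the caveolin gene cav3 by 0.81, the calsequestrin gene casq2 by 0.46 and the calcium pump gene atp2a2a by 0.41, and the mean was -0.16 (-0.28 under median scaling, adjusted p = 0.0774, 0.0131 with no filter on low values, 0.0331 with the lowest 50% left out, 0.0295 without hypoxia 3, and with all 10 arrays 0.0384 without and 0.0402 with the run as a block). Cardiac stress genes had 0 of 10 called in limma (0 higher and 1 lower adjusted over the list alone) and a mean of -0.26 (-0.43 under median scaling, adjusted p = 0.102, 0.0351 for the deposited values and 0.0295 without hypoxia 3). Skeletal muscle genes had 1 of 20 lower (1 adjusted over the list alone), the nucleoside diphosphate kinase gene nme2b.2 at -1.11, with a mean of -0.48 (adjusted p = 0.0838, 0.0118 for the deposited values, 0.0496 under cyclic loess, 2.09e-06 without normoxia 1, and with all 10 arrays 0.0309 without and 0.0386 with the run as a block). By run the skeletal muscle means were 0.14, -1.43 and -0.69, so the direction differed between runs.

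**Figure D3:**
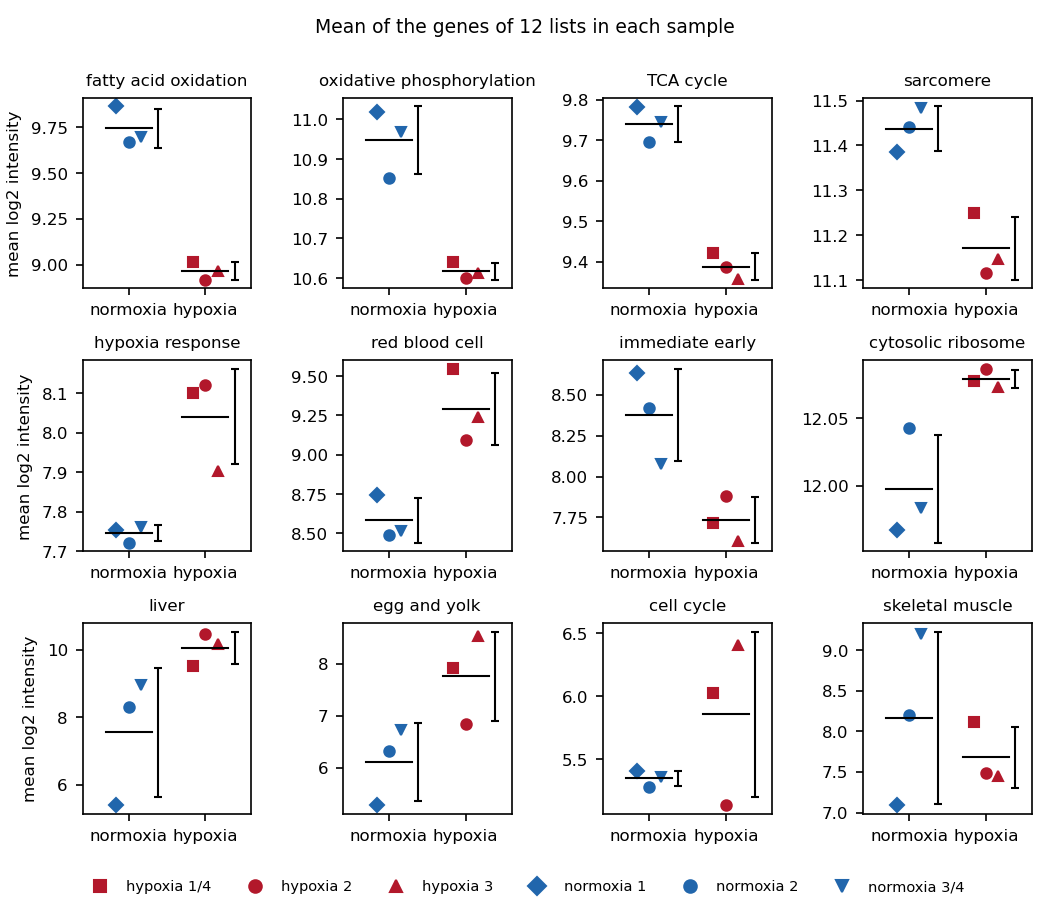
Mean log2 intensity of the genes of 12 lists in each of the 3 hypoxia and 3 normoxia samples, with the group mean as a line and the SD as a bar (n = 3), each panel on its own scale. The hypoxia samples of fatty acid oxidation lie below all normoxia samples, those of red blood cell genes above, and the liver list spans 3.59 log2 within normoxia.

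Transcripts of other tissues also differed. Liver genes had a mean of 2.5 and all 21 lay above 0, with 2 past the threshold, hpxa and hp (3 adjusted over the list alone, adjusted p = 3.43e-10, adjusted p = 0.336 with an estimated correlation). Their mean was 10.05 ± 0.48 in hypoxia against 7.55 ± 1.91 in normoxia (SD, n = 3), and 3.17, 0.87 and 2.14 higher in runs 1, 2 and 3. Egg and yolk genes had a mean of 1.65 (adjusted p = 0.000552, adjusted p = 0.309 with an estimated correlation) and 1.53, 1.48 and 0.63 by run. The list's 3 abundant members, vtg2, vtg3 and vtg4, are vitellogenin genes, which the liver transcribes, and the other 6 had means of 4.20 to 5.45 near the background bound of 4.81. Of 9, zgc:171776 passed (1 adjusted over the list alone), under the background bound on the normoxia arrays and at least 1.70-fold higher with values at that bound (adjusted p = 0.261, not past the threshold). Cell cycle genes had a mean of 0.51 and a median of 0.15 (adjusted p = 0.0177, adjusted p = 0.776 with an estimated correlation), with 0 of 32 called in limma and 0 adjusted over the list alone. The cell cycle call ended without hypoxia 3 (mean 0.10, adjusted p = 0.389) or hypoxia 1/4 (mean 0.31, 0.213), under cyclic loess (0.0506), with no filter on low values (0.0752), with the lowest 50% left out (0.192) and with all 10 arrays, both without (0.0594) and with (0.0708) the run as a block, and held in 20 of 29 settings. By run the cell cycle means were 0.31, 0.82 and -0.21. Run 3 holds only repeat arrays of sample 2, whose cell cycle mean was 5.13 in hypoxia and 5.28 in normoxia. Its opposite direction is thus that of sample 2 and not of a separate set of samples. The replication clamp gene pcna had 0.16 (adjusted p = 0.600, -0.05 under median scaling).

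Markers of other cell types in or near the heart were not past the threshold as lists. Gill and skin epithelium genes had a mean of 0.28 (0.11 under median scaling, adjusted p = 0.512, 0.0122 without hypoxia 1/4), with 1 of 15 called, epcam (1 adjusted over the list alone). Leukocyte genes had -0.09 (-0.21 under median scaling, adjusted p = 0.803) and endothelium genes 0.05 (adjusted p = 0.776, -0.04 under median scaling), with 0 of 21 and 0 of 11 called in limma and 0 adjusted over the list alone in either. Extracellular matrix genes had 0.04 (adjusted p = 0.234, 0.0397 without hypoxia 1/4), a mean that turned to -0.05 for the deposited values and to -0.12 under median scaling, with 0 of 26 called in limma and 6 higher and 2 lower adjusted over the list alone. Insulin-like growth factor genes had a mean of 0.15 and a median of -0.13 (adjusted p = 0.803, mean 0.04 under median scaling), with 1 of 9 called, igfbp1a (2 adjusted over the list alone). Of the epicardium markers aldh1a2 had -0.38, tbx18 -0.03 and krt4 0.24, 0 of 3 called in limma, and 1, lower, adjusted over the list alone.

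Camera called 11 of the 25 lists, 6 higher and 5 lower, and none of the 11 with an estimated correlation, under which 4 lists had an unadjusted p under 0.05. The limma fry test, which asks whether a list's genes move on balance one way, called 8 lists, 6 of them among the 11. It did not call the lists of cell cycle (adjusted p = 0.788), liver (0.127), egg and yolk (0.108), cytosolic ribosome (0.0641) and immediate early genes (0.0641). Beyond the 11 it called calcium and conduction (0.00909) and cardiac stress (0.0255). A sign of RNA quality separated the groups. The 3' to 5' log2 ratio of the GAPDH control probe sets was 0.81 ± 0.06 in hypoxia against 1.23 ± 0.33 in normoxia (SD, n = 3, exact permutation p = 0.1, the smallest that 3 against 3 samples can give), and that of the actin control was 0.43 ± 0.29 against 0.58 ± 0.42 (exact permutation p = 0.7). The samples of the 2 groups did not overlap in the GAPDH ratio, so it split the samples as each list above that separated the groups did. Whether the ratio followed the lists within a group was not tested.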

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

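The samples as labelled, the floor at the background bound and the near-identical arrays left out together were chosen after the data were seen, and the other alternatives were fixed before. The main count of 432 changed probe sets was 103 for the deposited values, 790 with median scaling, 171 with no filter on low values, 2 with no intensity trend in the limma fit (2181 at unadjusted p under 0.05), 1012 with all 10 arrays and the sample as a random block, 869 when the hybridization run was added to that fit as a block, 1397 with the 8 samples as labelled and 867 at adjusted p under 0.10. With the replicate number as a block over the 8 labelled samples it was 1071. The numbers did not pair the samples, since the correlations of deviations between samples of the same number were 0.178, 0.0932, 0.0757 and -0.0929. Leaving out 1 counted sample at a time, each a fit to fewer samples, gave 1 without hypoxia 3, 23 without normoxia 1, 82 without normoxia 3/4, 87 without hypoxia 1/4, 96 without normoxia 2 and 226 without hypoxia 2. Leaving out 1 array of a near-identical pair kept 3 against 3 samples and gave 379 (without hypoxia 4) to 421 (without hypoxia 1). The count stayed within 1.5 times the main one under cyclic loess (370), an offset of 50 (424), a filter of 50% (506), robust variances (487), array weights (486), the floor at the bound (371), a 1.5-fold minimum (289), 1 probe set per gene (341) and the other uses of array 5 (323 to 576). Where not stated, the cause of a shift was not tested. The count of 11 lists ran from 8 with fry to 13 with the replicate block, and was 11 or 12 with samples left out, but 0 with an estimated correlation (4 at unadjusted p under 0.05). Robust variances were not run for the lists, since camera has no such setting. No called gene of the 49, and no called list, changed direction past the threshold in any setting, though the ribosome mean turned to -0.06 under median scaling. Of the 49, 32 kept the call with the deposited values, 44 with cyclic loess, 47 with median scaling, 25 with the floor at the bound, 1 with no intensity trend, 46 with all 10 arrays with or without the run as a block, and 49 with the samples as labelled. Of the panel genes not called, vegfaa passed in 2 of 27 settings and ldha in 3. Their adjusted p ran from 0.0341 to 0.327 for vegfaa and from 0.00792 to 0.925 for ldha. Signal over background limits genes such as elf3 and wu:fb63a08, whose normoxia values lie under the bound, and myl7, mb and the adult globin genes sit near the top of the scale, where changes are compressed.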

Other observations

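The families in the next 2 paragraphs were picked by gene symbol after the data had been seen, and so were the tests of fatty acid oxidation against the sarcomere, of scaling, of egg RNA with and without vitellogenins and of red blood cell number, while the tests of oxidative phosphorylation and the TCA cycle against the sarcomere, of liver carry-over and of the splits were set before their results.

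Of 59 measured genes of the mitochondrial ribosome, which makes the proteins encoded by mitochondrial DNA, 12 fell (42 adjusted over the family alone), including mrpl48 at -0.93, mrps12 at -0.88, mrpl1 at -0.83 and mrpl37 at -0.77, and the others were not called. All 59 lay below 0, and 57 of 59 under cyclic loess, with a median of -0.39, beside a sarcomere mean of -0.27. No test of the family as a set was run, and a lower muscle share and the RNA quality, whose GAPDH ratio also separated the groups, were not tested against it. Among 20 mitochondrial carriers 3 fell, the aspartate and glutamate carrier gene slc25a12 at -0.92, slc25a55b at -0.93 and the phosphate carrier gene slc25a3b at -0.26 (8 adjusted over the family alone), and among 19 genes of mitochondrial protein import timm50 fell by 0.57 (3 adjusted over the family alone). In the cytosol the 8 subunits of the chaperonin that folds actin and tubulin lay above 0 with a median of 0.26, which was 0.05 for the deposited values and turned to -0.02 under median scaling, and cct6a rose by 0.41 (5 adjusted over the family alone). Among 61 translation factors 5 rose, the initiation factor genes eif3i at 0.46, eif3m at 0.42, eif3ea at 0.36 and eif3d at 0.34 and the translation inhibitor gene eif4ebp3l at 0.56 (11 adjusted over the family alone), with a family median of 0.18 that was 0.02 for the deposited values and turned to -0.05 under median scaling. Of 51 spliceosome genes sf3b6 rose, by 0.47 (0 adjusted over the family alone), with a median of 0.08 that turned to -0.05 for the deposited values and to -0.13 under median scaling.

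Other families had 0 calls in limma. These were 16 aminoacyl-tRNA synthetases with a median of -0.20, 14 tubulins (-0.07, 1 lower adjusted over the family alone), 6 keratins (0.10, and -0.12 under median scaling), 6 histones (0.09, and -0.12 under median scaling), 12 vacuolar ATPase subunits (-0.15), 4 peroxisome biogenesis genes (-0.18), 34 Rab GTPases (-0.08) and 25 ubiquitin-conjugating enzymes (0.01, and -0.18 under median scaling), and keratins, histones and ubiquitin-conjugating enzymes were below 0 for the deposited values too. The kinesin gene kif20a rose by 2.36 to 2.64 log2 over 27 settings and was called in each, while 0 of 32 cell cycle genes were called in limma in the main comparison. The chymotrypsinogen gene ctrb.1 fell while the trypsin gene prss1, also of the pancreas, had 1.26 (SE 0.41, adjusted p = 0.149).

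The fall of oxidative metabolism genes was weighed against a lower share of heart muscle RNA and against the scaling between arrays. Fatty acid oxidation fell by more than the sarcomere genes, with a difference of -0.511 log2 (SE 0.0877) and no overlap between groups. Against the 10 sarcomere genes below the top of the scale it was -0.444 (SE 0.102). The sarcomere genes were brighter, with a list mean of 11.44 in normoxia against 9.74 for fatty acid oxidation. Signals near the top of the scale understate changes, so this cannot decide whether a smaller muscle share was the whole cause. For oxidative phosphorylation and the TCA cycle the difference from the sarcomere genes was -0.0665 (SE 0.0655), so a lower muscle share and a lower expression per muscle cell cannot be told apart for these lists. Scaling as the whole cause is argued against, since the list mean nearest to the median of all probe sets lay at -0.319 from it over 3 lists and 3 other scalings, and against the median of each sample at -0.366 (SE 0.0495), with no overlap between groups in 9 of 9 cases, although camera with an estimated correlation called none of the lists there (adjusted p = 0.150 to 0.521). The deposited values and median scaling were nearly the same test against the sample median, at -0.915 and -0.916 for fatty acid oxidation. The 9 cases are thus not separate tests. A lower expression of fatty acid oxidation genes in hypoxic hearts was not tested apart from these comparisons and stays open. A difference in RNA quality stays open as well.

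Liver genes, abundant in hypoxia samples and in some normoxia samples, and egg genes were weighed as RNA carried over from other tissues, with 0 of the 21 liver and 0 of the 9 egg genes on another list and no heart free of such RNA to compare. The liver list spanned 3.59 log2 within normoxia, and its most abundant genes rbp4 and tfa had 11.99 ± 0.19 and 12.01 ± 0.23 in hypoxia against 11.19 ± 0.68 and 10.66 ± 1.14 in normoxia (SD, n = 3). Across the 21 genes, which are not independent replicates, the profile of normoxia 3/4 minus normoxia 1 followed that of hypoxia minus normoxia 1 with rho = 0.829. This met the rule for carry-over that was set before. Random lists and separate baselines were not part of that rule. Random lists had a median rho of 0.26, and 0.07% of them were as high. With separate baselines rho was 0.218, so carry-over of liver RNA and a response of these genes to hypoxia cannot be told apart. Cell cycle and egg list means had Pearson r = 0.803 over the 6 samples (exact permutation p = 0.0569, adjusted over 2 relations 0.0569), Spearman rho = 0.486 (exact permutation p = 0.356) and r = 0.890 without the 2 samples farthest from the median egg mean. For the 6 egg genes other than vitellogenins r was 0.968 (exact permutation p = 0.0264, adjusted 0.0528) and rho 0.657 (exact permutation p = 0.175), but r was -0.73 without the 2 farthest samples, so the relation rests on those and egg RNA in unequal amounts could not be told from other causes.

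The rise of red blood cell genes was weighed against more red cells with an unchanged profile and against the scaling. The 15 members other than hbbe2 below the top of the scale lay between 0.146 and 1.22, and none differed from the mean of the members past the threshold (smallest adjusted p = 0.225), but 95% intervals reached up to 1.85 from that mean, so for these genes more red cells and a changed red cell profile cannot be told apart. The embryonic globin gene hbbe2 rose by 1.003 more than that mean (adjusted p = 0.0304 from limma). That mean includes hbbe2 itself, the largest rise of the list, which makes this difference smaller. It also includes members near background, such as slc25a37 (mean log2 intensity 4.34), whose understated changes make the difference larger. The difference is also that of 1 member, named for its large rise. More red cells and a change in the red cells themselves were therefore not told apart for hbbe2 either. The other embryonic globin gene measured, hbae3, had 0.146 (SE 0.593), too wide a spread to tell whether embryonic globins in general differ. Scaling as the cause is argued against, since the list stayed at least 0.681 above the median of all probe sets under 3 other scalings, and against the median of each sample at least 0.632 (SE 0.139), with no overlap between groups in 3 of 3 cases, although camera with an estimated correlation did not call it there (adjusted p = 0.304 to 0.521). Here too the deposited values and median scaling were nearly the same test against the sample median, at 0.632 in both. A response of red cells to hypoxia and a difference in how much blood stayed in the dissected hearts remain open.

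Other splits of the 6 samples into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split, as the 1 split with as many, gave 432 changed probe sets, and the highest of the others gave 0. For the lists the real split gave 11, again as the 1 split with as many, and the others gave 7 to 10. Calls at the preset correlation thus arose for other groupings as well. Each other split put 2 samples of 1 treatment on the same side, so part of the hypoxia difference stayed in it. Neither count therefore shows how many calls arise with no difference.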
